A study of Saccharum officinarum with 2 samples.

How the data were processed

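Small RNA was sequenced from 2 samples of sugarcane vegetative axillary buds, 1 library of inactive buds at 0 days after planting (0-DAP) and 1 library of outgrown buds at 2 days after planting (2-DAP). Per the labels' protocols, each library was made from 10 µg of total RNA extracted with TRIzol, from which RNA of 19 to 28 nt was purified on a denaturing gel. A 5′-adenylated adapter was joined to the 3′ end by T4 RNA ligase and a second adapter to the 5′ end, followed by cDNA synthesis and PCR, per the labels' protocols. No molecular identifiers are named there. The deposited values are counts of reads per distinct sequence, not scaled, in 1 table per library. Each sequence is listed once, with lengths from 19 to 25 nt. The tool and settings for adapter trimming, any filter, aligner and genome build are not given in the sources used here. No reference genome was used here, so sequences carry no genome positions.

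The depth was 5615974 reads in the 0-DAP library and 4274873 in the 2-DAP library. One read corresponds to 0.178 and 0.234 reads per 1000000 reads (RPM), and a count of 0 allows up to 3 counts, or 0.534 and 0.702 RPM. Base N occurred in 262 and 171 reads. Shares have 95% exact Clopper-Pearson intervals. For shares of distinct sequences these treat each sequence as independent and do not cover the effect of depth. Ratios of RPM have 95% exact conditional binomial intervals, which cover counting error only. Because each group is 1 library, no test between groups and no p-value was computed, and a fixed rule of size took its place. A family was called higher or lower when its ratio was at least 2-fold, the whole interval lay beyond 1 and it had 100 or more reads in the 2 libraries together. A distinct sequence was called by the same fold and interval when it had 10 or more RPM in at least 1 library. A ratio against 0 reads was computed against the floor of 3 counts per library.

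Reads were assigned to 31 conserved plant miRNA families by 58 mature sequences written from general knowledge. A read matched when bases 2 to 19 of the mature sequence were present exactly, its start lay within 1 nt and its length was 19 to 24 nt. The source locus of a read shared between family members is uncertain, so families are reported. Lists of families were fixed by function: growth and phase change, auxin pathway, copper and stress, nutrient, silencing machinery, monocot-restricted and, as markers of another organ, reproductive phased siRNA triggers. Families with no more than 3 reads in both libraries did not enter a list. A list's median log2 ratio was ranked among 10000 random lists of the same size, as a description of these libraries. These were drawn from single sequences of 20 to 22 nt outside the families, among the 200 nearest in abundance to each family. The match is loose for abundant families. In 0-DAP buds the most abundant sequence outside the families had 6181 RPM, against 105093 RPM for miR159. The tasiARF was sought by its 16-nt start. Fragments of rRNA, tRNA and snRNA were exact sense matches to 15 segments, also written from general knowledge.

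The families named were those with 10 or more RPM in at least 1 library, with the main member given for the 6 most abundant families. Members of the lists below that level are given with their reads. Outside the families, the 5 distinct sequences with the largest ratio in each direction among those with 100 or more RPM were named. These rules, the lists, the comparisons and most alternatives were set before the data were examined.

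Dicer-type pairs were counted among distinct sequences of equal length, with 3′ overhangs from 0 to 6 nt. A longer overhang leaves a shorter paired stretch to match, so shares at different offsets are not fully comparable. Reads holding the last 11 bases of the Illumina 5′ adapter were counted as adapter reads. Sequence preference was described by the share of 24-nt distinct sequences with each first 4 bases. A logistic model was also fitted to 4-base words, with the first word kept apart from the rest, of 100000 24-nt sequences per library found in that library only, with 20% held out. Its area under the receiver operating curve on held-out sequences was 0.707. Its log2 odds for the main member of each family were subtracted from the log2 ratios of families and lists.

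The counting rule was tested on simulated data with known answers, for the 7765 distinct sequences of the 2-DAP over 0-DAP comparison. With 200 sequences changed by known folds, 57.5% were recovered at 2-fold and 100% at 4-fold and at 8-fold. Of unchanged sequences, 0.397%, 0.198% and 0.330% were called. The simulated libraries held counting noise only, without PCR copies, ligation preferences or other differences between libraries. These rates therefore do not give the share of false calls in the data. Alternatives covered the lengths in the denominator, removal of the 10 most abundant sequences of each library, of rRNA, tRNA and snRNA fragments and of single reads, thinning of the deeper library, scaling by the median of ratios, by reads of 20 to 24 nt, by reads outside rRNA, tRNA and snRNA and by conserved miRNA reads, the matching rule and the minimum count. Removal of adapter reads and of miR159 was added after the data were seen. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and scikit-learn 1.9.0, and plots Matplotlib 3.10.9.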

Results

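Small RNA populations were profiled in vegetative axillary buds of sugarcane. An axillary bud forms in the angle between leaf and stem and stays inactive until it grows out into a shoot. One library was made from inactive buds at 0 days after planting (0-DAP) and 1 library from outgrown buds at 2 days after planting (2-DAP). The 0-DAP library held 5615974 reads of 2580956 distinct sequences, and the 2-DAP library held 4274873 reads of 2515920 distinct sequences. With 1 library per stage there was no replicate check. Differences below therefore compare these 2 libraries, not the 2 stages, and the intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules. All deposited sequences were 19 to 25 nt long.

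The first comparison asked how the size classes of small RNAs differed between inactive and outgrown buds. In plants, 21-nt small RNAs include most microRNAs (miRNAs) and 24-nt small RNAs are mainly short interfering RNAs of the RNA-directed DNA methylation pathway. The 24-nt class was the most abundant in both libraries. It took 47.6% of 0-DAP reads (47.5% to 47.6%, Clopper-Pearson interval) and 52.6% of 2-DAP reads (52.5% to 52.6%). The 21-nt class took 24.2% of 0-DAP reads (24.1% to 24.2%) and 17.6% of 2-DAP reads (17.5% to 17.6%). The ratio of 24-nt to 21-nt reads was 1.97 in the 0-DAP library and 2.99 in the 2-DAP library. The 22-nt class differed less, at 15.4% and 14.4% of reads.

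A single miRNA family, miR159, supplied much of the 21-nt difference. When miR159 reads were left out of both libraries, the 21-nt share was 16% in 0-DAP and 13.6% in 2-DAP buds, and the 24-nt share was 53.1% and 55.3%. This removal was chosen after the data were seen. Without sequences of 1 read, the 24-nt share was 34.8% and 36.1%. The 24-nt share of distinct sequences was 67.0% in both libraries. Its difference of 0.0673 percentage points had a counting interval that included 0 (-0.0144 to 0.149). The difference was 0.357 points (0.270 to 0.444) with the 0-DAP library thinned to the 2-DAP depth. Without adapter reads it was 0.104 points (0.0226 to 0.186), and among sequences with 2 or more reads -3.54 points.

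**Figure D1:**
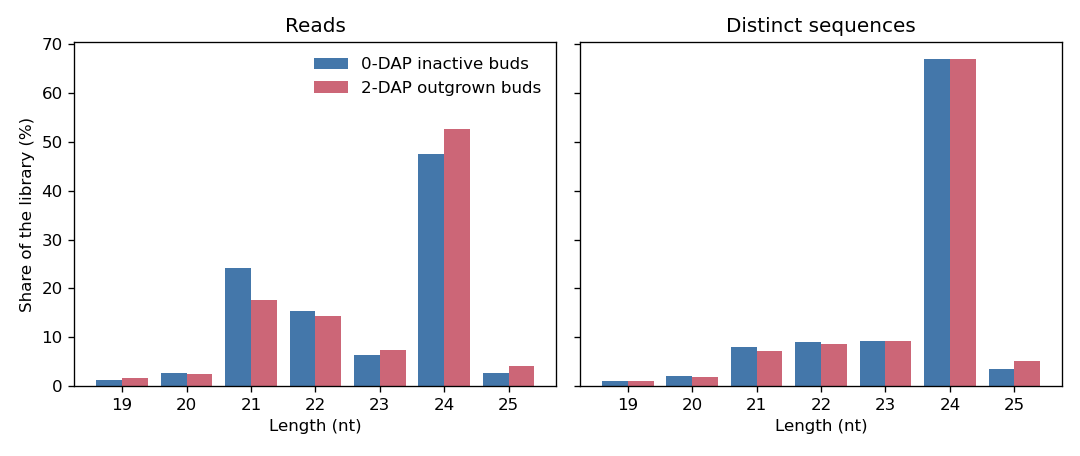
Share of the library (percent) at each length (nt), for reads on the left and distinct sequences on the right, with 1 library per stage. The bars at 21 nt stand at 24.2% of 0-DAP reads and 17.6% of 2-DAP reads, while the distinct-sequence bars at 24 nt stand at 67.0% in both.

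The next comparison concerned the 5′ base, the position that guides loading of small RNAs into different Argonaute proteins. A 5′ A began 43.6% of 24-nt reads in 0-DAP buds (43.6% to 43.7%) and 52.6% in 2-DAP buds (52.6% to 52.7%). A 5′ G began 35.7% of 24-nt reads in the 0-DAP library and 25.3% in the 2-DAP library. Among 21-nt reads, 5′ U began 65.5% (65.4% to 65.5%) in 0-DAP and 57.5% (57.4% to 57.6%) in 2-DAP buds. Without miR159, which begins with U, 5′ U among 21-nt reads was 41.7% in 0-DAP buds and 42.4% in 2-DAP buds, so the direction turned.

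The shift from 5′ G to 5′ A was not limited to 24-nt small RNAs. In the 2-DAP library 5′ A was more frequent in each of the 7 length classes and 5′ G less frequent in 6 of them. Among 21-nt reads 5′ G differed by -0.00711 percentage points, within counting error. Without miR159 it was 18.7% of 21-nt reads in 0-DAP and 15.0% in 2-DAP buds, and among 21-nt distinct sequences 23.1% and 18.8%. The first 4 bases of 24-nt distinct sequences differed as well. Sequences that began with GAAC made up 5.59% of the 24-nt distinct sequences of 0-DAP buds and 0.534% of those of 2-DAP buds, 10.5-fold lower. Those that began with GAAT were 4.73-fold lower in the 2-DAP library. Not every start with G was lower, since GCTC was 2.59-fold and GAGG 2.09-fold higher. The largest rise among all 4-base starts was that of CGGC, at 4.45-fold.

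**Figure D2:**
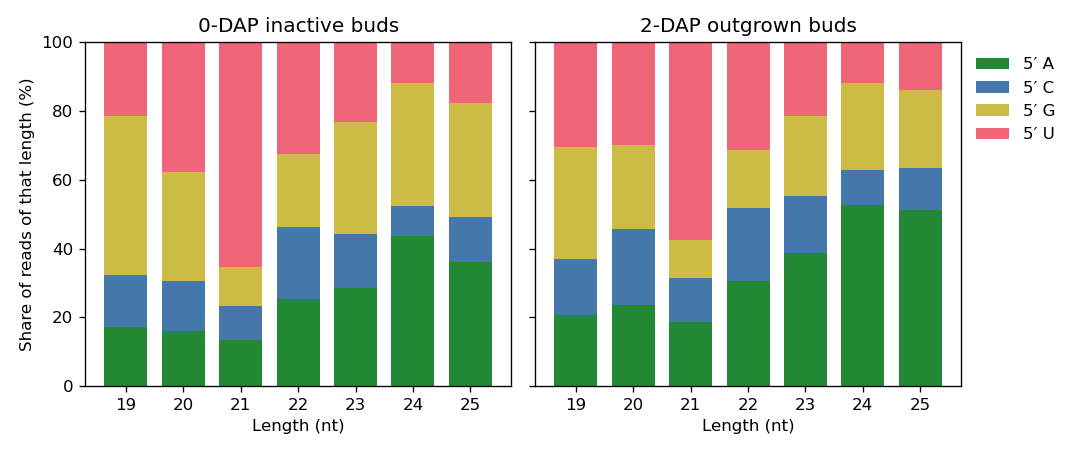
Share of reads (percent) that began with each base at each length (nt), in 0-DAP inactive buds on the left and 2-DAP outgrown buds on the right, with 1 library per stage. The 5′ A segment of the 24-nt bar spans 43.6% in 0-DAP and 52.6% in 2-DAP buds, and the 5′ G segment 35.7% and 25.3%.

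The overlap of the small RNA populations was then measured. Of 4755169 distinct sequences found in either library, 341707 were found in both, or 7.19% (7.16% to 7.21%). These shared sequences held 50.7% of 0-DAP reads and 40.0% of 2-DAP reads. Sharing was higher among 21-nt sequences (14.2%) and 22-nt sequences (14.4%) than among 24-nt sequences (6.31%). Most distinct sequences were seen once, 83.3% in 0-DAP and 86.4% in 2-DAP buds, so that the overlap is limited by depth. With the 0-DAP library thinned to the 2-DAP depth the shared part was 7.01%, outside the interval above, which does not cover depth. Among sequences with 2 or more reads, 16.8% were shared. At equal total reads the 2-DAP library held 2515920 distinct sequences against 2053671 in the 0-DAP library thinned to 4274873 reads. Reads of miR159 and PCR copies were not made equal, so this does not compare the diversity of the small RNAs themselves.

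Conserved miRNAs were compared to ask which families differed between inactive and outgrown buds. Reads of 28 of the 31 families searched were found. Together they went from 110341 reads per 1000000 reads (RPM) in 0-DAP buds to 57138 RPM in 2-DAP buds, a ratio of 0.518 (0.515 to 0.520). The family miR159, which targets transcripts of GAMYB transcription factors, set this total. It held 95.2% of conserved miRNA reads in 0-DAP buds and 86.1% in 2-DAP buds. Without miR159 the total turned direction, from 5248 to 7967 RPM, a ratio of 1.52 (1.49 to 1.54).

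Of the 14 families with 100 or more reads in the 2 libraries together, 6 were at least 2-fold higher in 2-DAP buds, 2 were at least 2-fold lower and 6 were neither. Scaling by the median of ratios over distinct sequences added 0.22 to every log2 ratio, and miR159 was then lower by less than 2-fold, which left 1 family in the lower group. The same scaling put 8 families in the higher group, with miR167 (log2 ratio 1.20) and miR394 (1.12) added. Scaling by the total of conserved miRNA reads added 0.95 to every log2 ratio. Most of those reads were miR159 itself, 95.2% in 0-DAP and 86.1% in 2-DAP buds. This scaling therefore holds miR159 near 0, at a log2 ratio of -0.15, and raises the other families by its fall. With it, 10 families were at least 2-fold higher and 0 lower. With a minimum of 10 reads in place of 100, 13 were higher and 3 lower.

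The 2 lower families are related in sequence. The family miR159 fell from 105093 to 49171 RPM, a ratio of 0.468 (0.466 to 0.470) and a log2 ratio of -1.10. Its most abundant member, TTTGGATTGAAGGGAGCTCTG, had 98103 RPM in 0-DAP buds and 45884 RPM in 2-DAP buds, and made up 93.3% of the family's reads in both libraries. The family miR319, which targets TCP transcription factors of leaf growth, fell from 2828 to 906 RPM, a ratio of 0.320 (0.309 to 0.332). Its main member was TTGGACTGAAGGGTGCTCCCT, with 2574 RPM in 0-DAP and 764 RPM in 2-DAP buds.

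The family of miR170 and miR171, here called miR171, targets GRAS transcription factors of the HAIRY MERISTEM group and showed the largest ratio among the families with 100 or more reads. It rose from 16.2 to 324 RPM, 20.01-fold (16.18 to 25.02). Both of its main members rose. TTGAGCCGTGCCAATATCACG went from 10.3 to 183 RPM, and TGATTGAGCCGTGCCAATATC went from 4.63 to 132 RPM.

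The family miR168, which targets ARGONAUTE1, rose from 1299 to 4175 RPM, 3.21-fold (3.13 to 3.30), with TCGCTTGGTGCAGATCGGGAC as its main member. The family of miR165 and miR166, here called miR166, which targets class III HD-ZIP transcription factors of meristem and leaf polarity, rose from 725 to 1781 RPM, 2.46-fold (2.36 to 2.55), with TCGGACCAGGCTTCATTCCCC as its main member. The family miR160, which targets AUXIN RESPONSE FACTOR transcripts, rose from 48.4 to 255.7 RPM, 5.28-fold (4.62 to 6.05), with TGCCTGGCTCCCTGTATGCCA as its main member. The family miR164, which targets NAC transcription factors of the CUP-SHAPED COTYLEDON group, rose from 8.01 to 40.5 RPM, 5.05-fold (3.62 to 7.18). The family miR827, which targets SPX-domain proteins of phosphate balance, rose from 22.8 to 91.2 RPM, 4.003-fold (3.27 to 4.93).

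The remaining families with 100 or more reads lay within 2-fold when scaled by all reads. The ratio was 1.97 (1.64 to 2.38) for miR167, 1.87 (1.28 to 2.73) for miR394, 1.34 (1.19 to 1.52) for miR162 and 1.14 (0.855 to 1.52) for miR529. The family miR393, which targets auxin receptors of the TIR1 group, had 13.9 and 8.66 RPM, a ratio of 0.623 (0.410 to 0.933) whose direction turned when scaled by the total of conserved miRNA reads. The family miR396, which targets GROWTH-REGULATING FACTOR transcripts, had 98.3 and 85.6 RPM, a ratio of 0.871 (0.761 to 0.996) whose direction turned under both of the scalings above. The family miR408, named because it exceeded 10 RPM, had 7 reads in 0-DAP and 52 reads in 2-DAP buds, too few for a call.

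The family ratios were set beside the sequence differences between the libraries' 24-nt small RNAs. A model of 4-base words fitted to 24-nt sequences found in 1 library gave each family's main member log2 odds of belonging to the 2-DAP library. After these log2 odds were subtracted, the log2 ratio went from 2.34 to 0.33 for miR164, from 1.30 to -0.09 for miR166 and from -1.10 to -0.46 for miR159. It stayed beyond 2-fold for 5 of the 8 called families, at 3.599 for miR171, 1.71 for miR827, 1.68 for miR160, 1.08 for miR168 and -2.11 for miR319. Among the families that were not called, the direction turned for miR162 (0.43 to -0.29), miR394 (0.90 to -0.90) and miR529 (0.19 to -0.86), and miR393 went from -0.68 to -1.10. In all, 8 of the 14 families lay below 0 after the subtraction, and of the 12 besides miR159 and miR319, called or not, 10 were above 0 before it and 6 after. The log2 odds were above 0 for every family but miR159 (-0.63), from 0.295 for miR827 to 2.01 for miR164. The subtraction therefore lowered all the other families together, which could only move miR319 further below 0. Across the 14 families the Pearson correlation of log2 odds with log2 ratios was 0.41, and 0.13 without the 2 farthest families.

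**Figure D3:**
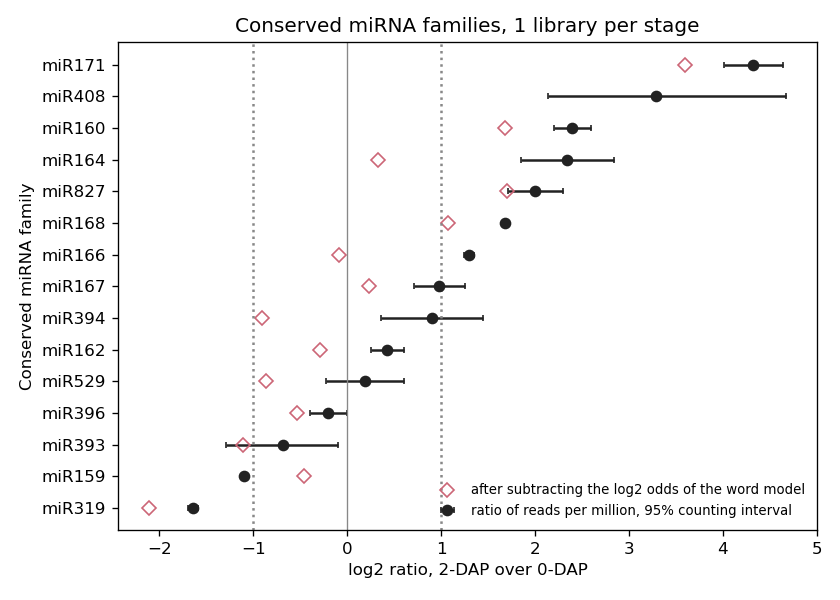
The log2 ratio of RPM, 2-DAP over 0-DAP buds, for the 15 named conserved miRNA families, as filled points with 95% counting intervals from 1 library per stage; open diamonds show the 14 families with 100 or more reads after the log2 odds of the word model were subtracted, and dotted lines mark 2-fold. The filled points run from -1.64 for miR319 to 4.32 for miR171; miR396 and miR393 change direction under another scaling, and the diamonds of miR159, miR164 and miR166 lie within 2-fold.

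Families were also read by function, in lists fixed before the data were examined. Of the 5 families of the auxin pathway, miR160 and miR164 rose and the other 3 did not pass the rule of size. The median log2 ratio of this list was 2.34, which is the value of miR164 from 45 and 173 reads. It lay at percentile 98.2 among 10000 random lists of the same size, loosely matched on abundance but not on the libraries' sequence preferences. The random lists themselves had a median of -0.79, so the percentile does not by itself show a rise. After the log2 odds of the word model were subtracted, the median of the auxin list was 0.33, again the value of miR164. Its other members were miR167 and miR393, given above, and miR390, the trigger of TAS3 trans-acting siRNAs, with 2 and 18 reads. The TAS3 siRNA that targets AUXIN RESPONSE FACTOR transcripts (tasiARF) was sought by 1 exact 16-nt start. Reads with this start numbered 0 in both libraries, which allows up to 0.534 RPM in 0-DAP and 0.702 RPM in 2-DAP buds. Variants with another start or a mismatch were not searched, so this does not limit tasiARF as a whole.

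In the list of growth and phase change, 10 of 11 families were measured. Of these, miR164, miR166 and miR171 rose and miR159 and miR319 fell. The median log2 ratio was 0.44, at percentile 93.5 against a random median of -0.91, and -0.39 after the log2 odds were subtracted. The random lists could not match the abundance of miR159. The phase-change families were scarce in both libraries, with 5.70 and 7.02 RPM for miR156, which targets SPL transcription factors, and 2.67 and 3.98 RPM for miR172, which targets AP2-type transcription factors. Neither difference exceeded counting error. The family miR535 had 0 reads.

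The 4 families of the copper and stress list each had fewer than 100 reads, so none could be called. All 4 had counting intervals above a ratio of 1. The families miR397 and miR398, which target laccases and copper superoxide dismutases, each had 0 reads in 0-DAP and 29 reads in 2-DAP buds, at least 12.7-fold higher against a floor of 3 counts in the 0-DAP library, with a lower counting limit of 9.68. For miR408 the ratio was 9.76 (4.42 to 25.5), and for miR528, with 5 and 15 reads, it was 3.94 (1.36 to 13.9). The median log2 ratio with miR397 and miR398 at their bound was 3.48, at percentile 97.9 against a random median of -0.0527, and 1.49 after the log2 odds were subtracted.

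In the nutrient list, miR827 rose. The sulfate family miR395 had 3.03 and 7.72 RPM, and the phosphate family miR399 had 8.37 and 1.87 RPM, a ratio of 0.224 (0.0913 to 0.478) from 47 and 8 reads. The list median was 1.35, the value of miR395 from 17 and 33 reads, at percentile 89.4 against a random median of -0.91. It was 0.0818 when only exact matches of the full mature sequence were counted and 1.69 after the log2 odds were subtracted. In the silencing machinery list, miR168 rose and miR162, which targets DICER-LIKE1, had the ratio of 1.34 given above. That list's median was 1.06, at percentile 83.8 against a random median of -0.85, and 0.39 after the log2 odds were subtracted. In the monocot list, 3 families were measured and none had 100 reads. Its median was 1.98, the value of miR528, at percentile 77.4 against a random median of -0.137, and 1.09 after the subtraction. The family miR444, which targets MADS-box transcripts, had 7 and 26 reads. The family miR437 went the other way, with 5 and 1 reads, a ratio of 0.263 (0.00556 to 2.35) within counting error. The triggers of reproductive phased siRNAs, included as markers of floral tissue, were near absent at this depth, with 1 read of miR2118 in 2-DAP buds and 0 reads of miR2275 in both libraries.

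Single small RNA sequences were compared next, whatever their class. Of 7765 distinct sequences with 10 or more RPM in at least 1 library, 2168 were at least 2-fold higher in 2-DAP buds, 4020 were at least 2-fold lower and 1577 were neither. Higher calls were thus 35.0% of all calls. At a minimum of 1 RPM they were 52.2%, with 30149 higher and 27577 lower sequences. By length, 26.9% of tested 21-nt sequences and 26.2% of tested 24-nt sequences were higher, and 51.7% and 53.8% were lower. The higher calls included 85 sequences that carry the end of the Illumina 5′ adapter and are not small RNAs of the bud. This number is a lower limit, since only exact adapter ends were counted.

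The 5 sequences with the largest ratios toward 2-DAP buds among those with 100 or more RPM all carried that adapter end. They were GTTCTACAGTCCGACGATCGAGA (1 read in 0-DAP and 4688 reads in 2-DAP buds), CTACAGTCCGACGATCGAGA (1 and 4399 reads), TCTACAGTCCGACGATCGAGA (0 and 10758 reads), TTCTACAGTCCGACGATCGAGA (0 and 10459 reads) and GAGTTCTACAGTCCGACGATCGAGA (1 and 2511 reads). Their order is not read, since those with 0 reads were set at the floor. Among sequences without the adapter end, chosen after the data were seen, TCATCCAGGTCCCTAAACATG had 2 reads in 0-DAP and 528 reads in 2-DAP buds, a ratio of 347 (95.5 to 2871). ATTCTTTGCAAGTGCCAGGGC had 3 and 549 reads, a ratio of 240.4 (81.8 to 1169). TGGGAAGTCCTCGTGTTGCATTCCC, whose first 21 bases match 5S ribosomal RNA, had 2 and 785 reads, and TGGGAAGTCCTCGTGTTGCATTCC had 10 and 1484 reads. GTTCTACAGTCCGACAATCGAGA, with 0 and 645 reads, resembles the adapter reads but does not hold the exact end.

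All 5 sequences with the largest ratios toward 0-DAP buds began with GAAC or GAAT, the starts that were depleted across the 24-nt sequences of the 2-DAP library. GAACAGCGGAGAGGTGCTGCCGAA had 1186 reads in 0-DAP and 1 read in 2-DAP buds, 903-fold lower (162 to 35688). GAACGCAGCAAGCACATCCGGGTG had 747 and 1 reads, GAATAATCAACAGGAAGAGAGGGT had 695 and 1 reads, and GAACGCAAGTTGCGCCCGAGGCC, a match to 5.8S ribosomal RNA, had 611 and 1 reads. GAACCAGCAGAAGCCGTTCCG had 655 and 0 reads, at least 166.2-fold lower against a floor of 3 counts in the 2-DAP library, with a lower counting limit of 134.8.

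Fragments of ribosomal RNA (rRNA), transfer RNA (tRNA) and U6 small nuclear RNA were followed as signs of RNA breakdown. They made up 0.508% of 0-DAP reads (0.502% to 0.514%) and 0.877% of 2-DAP reads (0.868% to 0.886%), a lower limit because the segments searched cover part of these RNAs. The individual RNAs went both ways. Fragments of 5.8S rRNA went from 1864 to 4948 RPM, 2.66-fold (2.59 to 2.72), and those of 5S rRNA from 597 to 996 RPM, 1.67-fold (1.59 to 1.74). Fragments from the start of 18S rRNA went from 846 to 459 RPM, a ratio of 0.542 (0.514 to 0.572).

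Among tRNAs, fragments of tRNA-Ala (anticodon AGC) rose from 155 to 1219 RPM, 7.85-fold (7.30 to 8.44). Those of tRNA-Glu (CTC) fell from 680 to 181 RPM, a ratio of 0.265 (0.245 to 0.287). Those of tRNA-Gly (GCC) had 666 and 798 RPM, a ratio of 1.20 (1.14 to 1.25). Of the tRNA-Ala fragments, 69.0% began at the first base of the tRNA in 0-DAP buds and 98.1% in 2-DAP buds. Of the tRNA-Glu fragments, 97.2% and 98.1% did so. Fragments of U6 fell from 194 to 48.9 RPM, a ratio of 0.252 (0.216 to 0.293), and in 0-DAP buds 63.7% of them were GAACGATACAGAGAAGATTAGCAT, which begins with GAAC.

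Pairs of small RNAs from opposite strands were counted to look for the 2-nt overhangs that Dicer leaves at 3′ ends. A partner at this offset was found for 1.40% of 24-nt distinct sequences in 0-DAP (1.38% to 1.42%) and 2.47% in 2-DAP buds (2.45% to 2.499%). The shares for 21-nt sequences were 7.28% (7.17% to 7.39%) and 9.63% (9.50% to 9.77%). These intervals treat sequences as independent, although both sequences of a pair are counted. The median of the other offsets was 1.59% and 2.73% for 24-nt sequences and 7.28% and 9.59% for 21-nt sequences. Longer overhangs tend to have higher shares because fewer bases must match, so the nearest offsets are the closer comparison. For 21-nt sequences the share at 2 nt exceeded those at 1 and 3 nt in 0-DAP (6.58% and 7.11%) and in 2-DAP buds (8.96% and 9.46%). For 22-nt sequences it was 7.56% and 10.3%, above 1 nt (6.65% and 9.15%) and 3 nt (7.16% and 9.70%) in 0-DAP and 2-DAP buds. For 24-nt sequences it was above 1 nt (0.879% and 1.67%) but below 3 nt (1.53% and 2.68%). The higher share of 2-DAP buds was present at each offset from 0 to 6 nt, so it was not specific to the Dicer offset.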

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

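The tests of miR159 removal, the gel slice, adapter reads, scaling, the number of libraries and pairing with the adapter end were chosen only after the result was seen, and the bound for the gel slice was raised from a quotient of 1 to 1.5 once its value was known; under the first bound that value would have counted against it. The tests of the first 4 bases and of the word model had their bounds set beforehand.

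Reads of the end of the Illumina 5′ adapter appeared in both libraries, a signal outside the small RNAs that were compared and above the limit that a count of 0 allows. Counted as exact matches, and so as lower limits, they made up 1.44% of 2-DAP reads and 0.00474% of 0-DAP reads. In the 2-DAP library 92.6% of them ran on into GAGA, and in the 0-DAP library 72.9% ran on into CTCA. They took 14.4% of 19-nt reads of the 2-DAP library and 0.273% of its 24-nt reads.

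The first pattern was the smaller 21-nt share of the 2-DAP library. Fewer miR159 reads alone do not account for it, since the share still differed by -2.37 percentage points without miR159, and neither do adapter reads, without which it differed by -6.66 points. A gel slice shifted to longer RNA stays open: without miR159 and adapter reads the 20-nt share ratio was 1.07 times the 21-nt share ratio, too close to 1 to decide without a second library. In those reads the ratio of shares, 2-DAP over 0-DAP, fell from 0.984 at 19 nt to 0.901 at 20 nt and 0.844 at 21 nt, which runs against such a slice, and was 0.880 at 22 nt, 1.08 at 23 nt, 1.05 at 24 nt and 1.48 at 25 nt, each above 21 nt, which runs with it. A change with bud outgrowth stays open and untested.

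The second pattern was lower miR159 and miR319 with 6 of the 12 other conserved families higher in 2-DAP buds by the rule of size. Scaling by one factor leaves the log2 gap of 2.39 (2.34 to 2.45) between miR159 and miR166, the nearest called families, as it is. None of the called families changed direction under any scaling tried, with miR159 at -0.15 and miR319 at -0.69 per conserved miRNA reads. This outcome was fixed by the calls, which required at least 2-fold, since the largest shift of any scaling tried was 0.95 in log2. The gap between a higher and a lower called family is set above 0 by the same rule. Neither value therefore decides whether scaling by the library total set the directions. Whether the gap exceeds the variation between libraries of 1 stage stays open, since no second library gives a spread to hold it against. The 2-fold size of miR159 did depend on scaling: its ratio was 0.468 (0.466 to 0.470) per all reads and 0.544 (0.541 to 0.546) by median of ratios, which moved it across the 2-fold line and ended that call. Differences in the first 4 bases do not account for the whole pattern, because subtracting them left 0.890 of the median absolute log2 ratio. That subtraction did move miR159 from -1.10 to -0.74, within 2-fold, while the other called families stayed beyond 2-fold. Of the families not called, miR167 (0.98 to 1.09) and miR393 (-0.68 to -1.04) moved beyond 2-fold. The wider word preferences of the libraries left 0.748 of the median absolute log2 ratio, between the bounds of 0.5 and 0.8. These preferences may account for part, with miR164, miR166 and miR159 moving within 2-fold. The log2 odds were above 0 for every family but miR159, so the subtraction lowered the others together. Their Pearson correlation with the log2 ratios was 0.41, and 0.13 without the 2 farthest families. With 1 library per stage, preparation and bud stage cannot be told apart, and a change with outgrowth remains a hypothesis, with miR171, miR319, miR827, miR160 and miR168 the 5 families that stayed beyond 2-fold after that subtraction.

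The third pattern was more 5′ A in each length class of the 2-DAP library and less 5′ G in each class but 21 nt, where it was lower only once miR159 was left out (18.7% and 15.0% of reads) or among distinct sequences (23.1% and 18.8%). Adapter reads with the exact end do not account for it, since without them 13 of these 13 differences stayed beyond 1 percentage point, among them 5.93 points for 5′ A and -8.65 points for 5′ G at 19 nt. The first 4 bases varied between libraries 1.98 times as much as the last 4, just under the bound of 2, so ligation differing at the 5′ end is not decided. The quotient depends on this baseline, and the last 4 bases themselves adjoin the 3′ adapter. The SD of log2 ratios was 0.546 for the first 4 bases, 0.373 for bases 5-8 and 0.290 for bases 11-14. It was 0.248 for bases 17-20 and 0.275 for the last 4. Whether RNA paired with library-specific bases at the end of the 5′ adapter, GAGA in 2-DAP and CTCA in 0-DAP buds, also stays open: inside 24-nt sequences the mean log2 ratio of words complementary to the 2-DAP end exceeded that of words complementary to the 0-DAP end by 1.21, against 0.33 at the 95th percentile of random words, but as the first 4 bases the difference was -0.24, the other way, with all 4 words of the 0-DAP end above 0 and 2 of the 4 of the 2-DAP end. A change in Argonaute loading with outgrowth remains open and untested.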

How the results depend on the processing

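Alternatives without adapter reads or without miR159 were chosen only after the data were seen. Of 85 alternative values for 20 results, 40 stayed within counting error or within 1.5 times the count, 42 moved beyond that without a change of direction and 3 turned direction. The causes were not tested unless the removal itself shows them. No paired analysis was possible because each group is 1 library, and for the same reason no library could be left out. The tasiARF ratio gave no value under any scaling, since the exact start searched had 0 reads, and the 19 to 28 nt window removed nothing.

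The direction turned for 5′ U among 21-nt reads without miR159 (0.696 points), for conserved miRNA RPM without miR159 (ratio 1.52) and for the 24-nt share of distinct sequences with 2 or more reads (-3.54 points; 0.357 when thinned). The 24-nt share of reads differed by 6.23 points within 20 to 24 nt, 2.51 without the 10 most abundant sequences, 5.19 without rRNA, tRNA and snRNA, 1.25 without single reads, 5.62 without adapter reads and 2.14 without miR159. The 21-nt share differed by -6.53 points within 20 to 24 nt, -2.39 without the 10 most abundant sequences, -5.41 without single reads, -6.66 without adapter reads and -2.37 without miR159. In the same removals 5′ U among 21-nt reads differed by -1.65 (most abundant), -6.59 (single reads) and -8.56 points (adapter), and 5′ A among 24-nt reads by 11.8 points without single reads. The shared part of distinct sequences was 7.01% when thinned and 16.8% with 2 or more reads. The 2-nt-overhang share differed by 1.21 and 1.99 points in these settings for 24 nt and by 2.71 and 3.35 points for 21 nt.

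The conserved miRNA ratio was 0.602 by median of ratios, 0.528 per 20 to 24 nt reads, 0.525 per reads without adapter, 0.522 with exact matches and 0.523 with up to 2 mismatches. Families at least 2-fold lower numbered 1 by median of ratios and 0 when scaled by the total of conserved miRNA reads, where 10 were higher. With a minimum of 10 reads, or none, 13 were higher. Distinct sequences numbered 30149 higher and 27577 lower at 1 RPM and 66 and 129 at 100 RPM. The rRNA, tRNA and snRNA share differed by 0.356 points with 1 mismatch, 0.326 without the most abundant fragment and 0.382 without adapter reads. By median of ratios the list medians were 2.55 for auxin and 1.27 for silencing machinery, and with exact matches 0.0818 for nutrient. Depth limits families below 100 reads.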

Other observations

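The features in this part were chosen only after the data were seen.

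An abundant group of small RNAs outside the conserved families shared the core GCAATTCGTCGAAC. It held 1.05% of 0-DAP reads and 0.775% of 2-DAP reads in 441 distinct sequences, more than any conserved family but miR159. Its members went in different directions. TGGAAGCAATTCGTCGAACAG, the most abundant sequence outside the families in both libraries, went from 6181 to 3590 RPM, a ratio of 0.581 (0.570 to 0.592). AGCAATTCGTCGAACAGCTGG went from 1614 to 345 RPM, and GGAAGCAATTCGTCGAACAG from 785 to 51.9 RPM, a ratio of 0.0662. TGGGGGAGCAATTCGTCGAAC went from 29.4 to 501 RPM, 17.05-fold (14.5 to 20.1), TGGAAGCAATTCGTCGAACGA from 482 to 1322 RPM, and TGGAAGCAATTCGTCGAACAGC, 1 base longer than the main sequence, from 382 to 1216 RPM. Without a genome the group has no assigned locus.

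Length variants of 1 miRNA also differed in ratio. For miR168, the form with an added 5′ base, ATCGCTTGGTGCAGATCGGGAC, went from 1.96 to 45.8 RPM, a ratio of 23.4 (12.8 to 47.7), against 3.41 for TCGCTTGGTGCAGATCGGGAC and 1.07 for CGCTTGGTGCAGATCGGGAC. For miR319, CTTGGACTGAAGGGTGCTCCCT had a ratio of 2.33 (1.84 to 2.97) while TTGGACTGAAGGGTGCTCCCT had 0.297 (0.286 to 0.308). The full-length share of miR159 differed by -0.0345 percentage points between the libraries.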
